A study of Mus musculus with 5 samples.

How the data were processed

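Single T cells from the brain parenchyma of 5 mice, with the choroid plexus left out, were profiled by a plate-based single-cell RNA sequencing method (MARS-seq type) in which RNA is barcoded per well, amplified linearly and counted by unique molecular identifiers (UMIs). Per the labels' protocols, mice of a strain with loxP-flanked glucocorticoid receptor alleles received TAT-CRE, a cell-permeable Cre recombinase, or PBS into the brain ventricles. They were then exposed to foot shocks, and cells positive for CD45 and the T cell receptor beta chain and negative for CD11b were sorted 1 per well on day 14 after the stress. The labels give each library its own replicate number, which names it here, and an age of 18, 18 and 19 weeks for TAT-CRE 207, 208 and 215 and of 19 and 16 weeks for PBS 216 and 218. Each library was taken as 1 mouse; whether a library pooled animals is not stated in the labels. The replicate numbers are not shared between the groups, so nothing pairs the mice, and every mouse had a sequencing library of its own in the same sequencing batch. Each mouse also had a plate and an amplification batch of its own. Effects of plate or amplification therefore cannot be told apart from differences between mice.

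The deposited values are raw UMI counts per gene and well, made by the authors; per the submitters' processing notes, bcl2fastq 2.15.0.4 and the mouse genome build mm10 were used. The aligner, the gene annotation and any filter on reads are not given in the sources used here, nor whether counting used the strand. Genes that overlap, or that lie antisense to another gene, can therefore share counts. Near copies can do so too (Ifit3 and Ifit3b, Ifit1 and Ifit1bl1, Ifi203 and Ifi204, Trbc1 and Trbc2, H2-K1 and H2-K2), and the counts of these genes are uncertain to that extent. Per the file headers, a deposited column of counts gives the number of cells sorted into each well: each plate of 384 wells held 380 wells with 1 cell and 4 empty wells. Of 15952 genes with a UMI in kept cells, 15260 (95.7%) were found by name in the GENCODE M21 annotation of the same build, from which coordinates and gene types were taken.

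Kept cells were wells labelled as holding 1 cell, with at least 400 UMIs outside spike-ins and at most 30% of UMIs from mitochondrially encoded genes. The UMI minimum removed 15, 48 and 22 wells of TAT-CRE 207, 208 and 215 and 36 and 102 of PBS 216 and 218. The mitochondrial limit then removed 54, 29 and 60 and 48 and 4. PBS 218 had 69 wells under 100 UMIs, against 6 to 8 in each of the other mice. The 20 empty wells held 17 to 160 UMIs each, and none of them had a UMI of Cd4, Foxp3, Il17a, Il17f, Ifng or Csf2, while Cd8a had one in 1, Cd8b1 in 2 and Ccl5 in 3 of these wells. Spurious UMIs can therefore make up a noticeable part of the shallowest cells. Ribosomal RNA genes (Gm42418 and Gm26917 on chromosome 17, mt-Rnr1 and mt-Rnr2) took 28.3% of the kept UMIs in TAT-CRE 208 and 43.9% to 48.0% in the other 4 mice. They were counted in the main tests and left out in an alternative. Pairs of libraries differed far beyond sampling noise, so the 5 libraries are separate. Chi-square per degree of freedom was 11.4 to 13.4 in pairs with TAT-CRE 208 and 4.42 to 6.50 in the others. It was taken over genes with at least 50 UMIs in the 5 mice together. The ribosomal RNA genes were included, so their lower share in TAT-CRE 208 can raise the values of that mouse.

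Kept cells were clustered (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15) on 151 genes of the fixed lists found in at least 1% of cells, with counts limited to 3, negative binomial residuals, 3 principal components (those above permuted data), 15 neighbours and a resolution of 1, which gave 17 clusters. A cluster was called X-like where at least 3 markers of X, fixed before the data were examined along with the gene lists, the tests and the rule for named genes, were enriched (Fisher's exact test over cells, p threshold 0.01) and where the 10 genes leading the cluster, among genes in at least 10% of all kept cells, held no more markers of another class than of X. A CD4, CD8 or naive name also needed more enriched markers of its own than of the rival lineage. These clustering steps were chosen after the data had been seen. Of 4 gene sets tried for clustering, the one on the fixed lists was taken because it best separated the fixed CD4, CD8 and naive markers. The naming rule was revised once after clusters and their sizes per mouse were known. The limit of 10% was set after others had been looked at, and CD8 T-like cluster 12 fails at 3%. A regulatory name was made to need more regulatory than CD4 markers; the earlier form of the rule would have given it to cluster 11. No gene or list had been compared between the groups at that point. Shares of cells with a UMI of the genes used for clustering describe the clusters and are not results. Such genes are named as used for clustering where a comparison of single genes within a class takes them. Most lists compared within classes hold such genes too. No doublet caller was run, because wells received 1 cell each; 25 cells (1.69%) had UMIs of both Cd4 and a Cd8 gene.

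Counts were summed per mouse over all kept T cells, over CD4 T-like and over CD8 T-like cells, and tested with edgeR 4.0.16 (R 4.3.3): genes kept by filterByExpr with a minimum count of 10, TMM scaling, robust quasi-likelihood fit and test of TAT-CRE against PBS with no covariate, and Benjamini-Hochberg adjustment at 0.05. Expression is given as counts scaled to a total of 1000000 UMIs (CPM), with TMM-scaled totals for single genes, as mean ± SD over 3 TAT-CRE and 2 PBS mice. A log2 fold change is TAT-CRE over PBS, with its standard error (SE) taken as its size divided by the square root of the test's F. Where no PBS mouse had a UMI, the fold is a lower bound against a floor of 3 counts over the PBS group. Where a group held 1 to 3 UMIs, the ratio of scaled totals has a 95% exact binomial interval for counting error. Named genes are, in each direction, the 10 called genes with the smallest p, or, where fewer are called, those of smallest unadjusted p up to 5. To these come 16 fixed genes and, for each list, its called members or else its 2 members of highest count. Pseudogenes and unnamed gene models were counted but not named, and a few genes that the rule takes are not reported here.

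Of 19 gene lists, 16 with at least 3 tested members were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01. The number of higher members, the median and the mean beside a list test are those of the voom values. Shares of cells were compared by a two-sided exact permutation test of the group means. With 3 mice against 2 there are 10 splits, and p cannot go below 0.1. Shares of cells with a UMI of a gene were compared after thinning each cell to 400 UMIs and are also given unthinned. Classes taken from the UMIs of each cell were not thinned. Intervals of shares are 95% exact (Clopper-Pearson) and, like the limits that a count of 0 allows (3 counts of the total), cover counting error only. A further fit tested whether the treatment effect differed between CD4 T-like and CD8 T-like cells. The level of each of 21 marker lists is given as CPM of all UMIs outside the ribosomal RNA genes, without TMM scaling.

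The gene tests were checked on simulated counts with the real means, library sizes and spread, in which 200 genes were changed. Over all T cells edgeR recovered 10.4% of genes changed 2-fold, 40.3% of those changed 4-fold and 68.2% of those changed 8-fold (5687 genes). In CD4 T-like cells it recovered 2.99%, 37.3% and 54.5% (1084 genes), and in CD8 T-like cells 2.99%, 28.4% and 59.1% (1229 genes). In these runs it also called 4 unchanged genes over all T cells, 1 in CD4 T-like and 5 in CD8 T-like cells. With nothing changed it called 0 genes in each. With the type I interferon list raised in simulated counts, camera called 2 lists, the raised one included, and 0 lists with nothing changed. The simulated genes varied independently of each other, close to the preset correlation. In the real counts the correlation estimated for the interferon list was 0.376. The simulation therefore cannot show how often camera calls lists falsely here.

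Alternatives set before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, minimums of 200 and 800 UMIs per cell, age as a covariate, thinning of each mouse to the smallest total, other clustering resolutions, classes taken from the UMIs of each cell, other thinning and cytokine choices, an estimated correlation, fry, and leaving out each mouse in turn. Added after seeing the data were no mitochondrial limit, the ribosomal RNA genes left out, the other gene sets for clustering, thinned totals for the list tests, an estimated correlation and an adjustment over both classes for the lists within classes, and leaving out TAT-CRE 208 and PBS 218 together. No sample and no count column was left out of the main tests.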

Results

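T cells from the brain parenchyma were compared between 3 foot-shocked mice that had received TAT-CRE into the ventricles and 2 foot-shocked mice that had received PBS. The aim was a knockdown of the glucocorticoid receptor at the choroid plexus, the epithelium that makes cerebrospinal fluid. The series title concerns T cells that enter the brain after stress and do not promote inflammation there. A total of 1482 cells were kept: 311, 303 and 298 from TAT-CRE 207, 208 and 215 and 296 and 274 from PBS 216 and 218. The wells of these mice held 776405, 395090, 679626, 617245 and 857632 UMIs in that order. Kept cells had a median of 1953, 993 and 1600.5 UMIs in the TAT-CRE mice and 1410 and 2660 in the PBS mice, with a median of 448, 294, 373, 352 and 510 genes. TAT-CRE 208 was the shallowest library and PBS 218 the deepest, and the groups overlapped in depth (exact permutation p = 0.5 for the median). TAT-CRE 208 also stood apart from the other libraries, with chi-square per degree of freedom of 11.4 to 13.4 in its pairs against 4.42 to 6.50 in all others. Its lower share of ribosomal RNA counts (28.3% against 43.9% to 48.0%) can contribute to these values.

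Nr3c1, which encodes the glucocorticoid receptor (mm10 chromosome 18, 39410545 to 39519421), gave 121, 51 and 92 UMIs in TAT-CRE 207, 208 and 215 and 106 and 186 in PBS 216 and 218. Its level was 163 ± 41.7 CPM (SD, n = 3) in TAT-CRE mice and 222 ± 14.4 CPM (SD, n = 2) in PBS mice, and each TAT-CRE mouse lay below both PBS mice. The log2 fold change of -0.44 ± 0.29 (SE) did not pass edgeR's quasi-likelihood test (adjusted p = 0.999). The cells are sorted T cells from tissue without choroid plexus, and whether the counted tags lie in the part between the loxP sites is not given, so these values check nothing about the knockdown. Of the genes that glucocorticoids induce, Tsc22d3 (GILZ) stood at 266 ± 29.4 CPM against 273 ± 24.8 CPM, and Fkbp5, a chaperone that restrains the receptor, at 46.5 ± 14.8 CPM against 33.9 ± 28.5 CPM. Neither passed the test (edgeR adjusted p = 0.999 for both).

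The cells carried T cell transcripts in every mouse. Trbc2, a constant segment of the T cell receptor beta chain, had a UMI in 55.3% of cells, and the T cell marker list stood at 8161 ± 109 CPM outside the ribosomal RNA genes in TAT-CRE mice and 8680 ± 1012 in PBS mice (exact permutation p = 0.5). Markers of other cells were measured beside them, although the sort on CD45, the T cell receptor beta chain and absent CD11b would remove most such cells. Neutrophil markers had no UMI in the 1482 cells, which does not exclude rare cells at this depth. Astrocyte, neuron and erythroid markers stayed at or under 9.97 CPM in each mouse, dendritic cell markers at or under 24.0 and choroid plexus markers at 14.2 ± 6.21 against 14.2 ± 8.09. Microglia markers stood at 55.7 ± 47.1 against 108 ± 68.3, oligodendrocyte markers, led by Mbp, at 355 ± 30.3 against 407 ± 82.3, endothelial markers, led by Ly6c1, at 241 ± 154 against 181 ± 134 and monocyte or macrophage markers at 1103 ± 282 against 1290 ± 105, the last led by Ly6c2, which memory CD8 T cells also express. B cell markers, led by Ighm, were at 260 ± 97.1 against 160 ± 10.6. The plasma cell list was Xbp1 alone, which T cells also express, at 51.6 ± 15.1 against 98.0 ± 11.7; its other 5 genes had no UMI in any cell. NK cell markers stood at 372 ± 159 against 568 ± 131, gamma delta T cell markers at 191 ± 91.8 against 312 ± 123, cycling cell markers at 337 ± 50.1 against 379 ± 112 and tissue-resident memory markers at 2551 ± 542 against 2321 ± 124. The CD4 T cell markers were at 941 ± 95.7 against 601 ± 192 CPM, the CD8 markers at 2461 ± 849 against 2658 ± 334, the regulatory markers at 737 ± 192 against 516 ± 133 and the naive markers at 1612 ± 101 against 1894 ± 617. The CD4 list, Xbp1 and the erythroid list, of which no gene had a UMI in more than 2 cells, reached the smallest p that an exact permutation test of 3 against 2 mice can give (p = 0.1), before any correction over the 21 lists.

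Which T cells were present was taken from the clusters. CD8 T-like cells made up 19.6% of kept cells (290 cells); 60.3% of them had a UMI of Cd8a, 30.7% of the granzyme gene Gzmk and 2.76% of Cd4. CD4 T-like cells made up 12.4% (184 cells); 22.3% had a UMI of Cd4, 6.52% of Cd8a and 11.4% of Cd8b1. Among 20 empty wells Cd8a had a UMI in 1 and Cd8b1 in 2, so some of these Cd8 UMIs can be background. The 2 clusters of the class differed, however. Cluster 5 (103 cells, 40 of them from TAT-CRE 208) had a UMI of Cd4 in 15.5% and of Cd8b1 in 16.5% of cells. Cluster 11 (81 cells) had them in 30.9% and 4.94%. Cluster 5 may therefore hold CD8 T cells too, and the class may be mixed. The unnamed cluster 8 (94 cells) had Cd4 in 21.3%, Cd8a in 14.9% and Cd8b1 in 5.32% of cells, so it may be mixed too. Cluster 5 was led by the interferon-inducible genes Ifi27l2a and Psme2 and cluster 11 by the early response genes Rgs2, Nfkbia and Fos. Naive T-like cells made up 20.8% (308 cells), and 45.8% of them had a UMI of Tcf7, a transcription factor of naive and memory cells. The 9 clusters without a name held 47.2% of cells, with 47.5 ± 2.06% in TAT-CRE mice and 46.7 ± 5.64% in PBS mice. Of these unnamed cells 27.0% had a UMI of Cd8a and 6.57% of Cd4, and of naive T-like cells 18.8% and 4.87%. The CD4 T-like and CD8 T-like classes therefore leave out many cells with a Cd4 or Cd8 UMI. Their shares are not those of all CD4 or CD8 T cells. No cluster was named regulatory, and none was named for a cell other than a T cell. Cluster 11, with 11, 23 and 24 cells in the TAT-CRE mice and 10 and 13 in the PBS mice, had Foxp3 and 4 more regulatory markers enriched beside 5 CD4 markers.

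The share of CD4 T-like cells was 14.7 ± 6.77% in TAT-CRE mice (SD, n = 3) and 8.99 ± 1.73% in PBS mice (SD, n = 2). It was 7.40% (95% interval 4.75 to 10.9), 20.8% (16.4 to 25.8) and 15.8% (11.8 to 20.4) in TAT-CRE 207, 208 and 215, and 7.77% (4.99 to 11.4) and 10.2% (6.90 to 14.4) in PBS 216 and 218. CD8 T-like cells made up 19.2 ± 11.3% against 19.8 ± 6.86%, with 31.5% (26.4 to 37.0), 9.24% (6.23 to 13.1) and 16.8% (12.7 to 21.5) against 24.7% (19.9 to 29.98) and 14.96% (11.0 to 19.7). Naive T-like cells made up 18.7 ± 3.11% against 24.5 ± 10.8%. For each class other splits of the mice gave a difference at least as large (exact permutation p = 0.4 for CD4, 1 for CD8 and 0.4 for naive T-like cells). With classes taken from each cell's own UMIs, cells with Cd4 and no Cd8 UMI made up 7.02 ± 0.725% against 3.66 ± 1.04%, higher in 3 of 3 TAT-CRE mice than in either PBS mouse (exact permutation p = 0.1, the smallest possible). Cells with a Cd8 and no Cd4 UMI made up 41.0 ± 15.5% against 44.7 ± 0.785% (exact permutation p = 0.7). These shares by each cell's own UMIs were not thinned. Median depth ran from 993 UMIs in TAT-CRE 208 to 2660 in PBS 218, so depth can enter them. The difference of -0.636 percentage points for CD8 T-like cells changed its sign without TAT-CRE 208 (4.33), TAT-CRE 215 (0.563) or PBS 216 (4.21), and in 6 other settings. The difference of 5.66 percentage points for CD4 T-like cells became 2.59 without TAT-CRE 208, 9.29 without TAT-CRE 207, 3.33 without a mitochondrial limit and 1.88 without the ribosomal RNA genes.

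**Figure D1:**
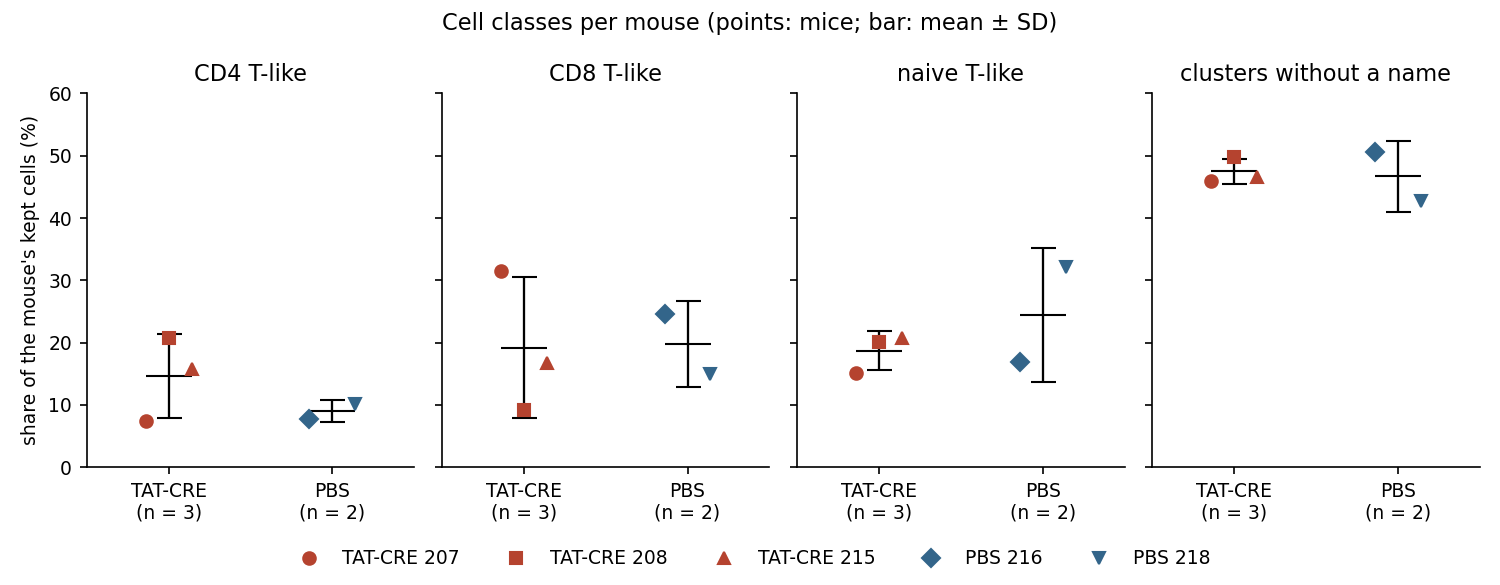
Share of kept cells (percent) that fell into the CD4 T-like, CD8 T-like and naive T-like classes and into clusters without a name; each point is 1 mouse, and lines with bars give the mean and SD of 3 TAT-CRE and 2 PBS mice. The CD8 T-like share runs from 9.24% to 31.5% among the TAT-CRE mice, a range that takes in both PBS mice.

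Regulatory T cells were followed by Foxp3, their defining transcription factor, since no cluster took that name. Without the mitochondrial limit 1 cluster of 84 cells did, with a share of 5.96 ± 2.74% against 3.61 ± 0.997% (exact permutation p = 0.3). With the limit, Foxp3 had a UMI in 7 cells of TAT-CRE 208, 8 of TAT-CRE 215 and 3 of PBS 218, and in none of TAT-CRE 207 or PBS 216, which allows shares of cells with a UMI up to 0.965% and 1.01% there. A cell without a Foxp3 UMI may still express it at this depth. That is 15 of 912 cells in TAT-CRE mice and 3 of 570 in PBS mice. After thinning to 400 UMIs the share was 0.865 ± 0.753% against 0.104 ± 0.148% (exact permutation p = 0.4), a difference of 0.761 percentage points that became 1.19 without TAT-CRE 207, 0.506 without TAT-CRE 208 and 0.426 with a minimum of 200 UMIs and thinning to 200. Unthinned it was 1.66 ± 1.45% against 0.547 ± 0.774% (exact permutation p = 0.5). Among CD4 T-like cells 4.89% had a Foxp3 UMI (median 1783 UMIs per cell), against 0.690% of CD8 T-like cells (median 1893.5 UMIs), which should lack it; Foxp3 was among the genes used for clustering, so this contrast is partly built in. The gene Il10, for a regulatory cytokine, gave 1 UMI, in TAT-CRE 207.

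Cytokines of encephalitogenic T cells, which drive brain inflammation in experimental models, were rare. Il17a, Il17f, Ifng or Csf2 had a UMI in 25 of 1482 cells, 1.69% (95% interval 1.09 to 2.48), namely 7, 9 and 1 cells of TAT-CRE 207, 208 and 215 and 4 and 4 of PBS 216 and 218. Il17a was found in 10 cells, 8 of them in TAT-CRE 208, and Il17f in 12 cells, 6 of them in TAT-CRE 207. Ifng had a UMI in 2 cells, and Csf2 in 1 cell of TAT-CRE 215 and in 0 of 570 cells of PBS mice, which allows a share up to 0.526%. After thinning the share of cells with any of the 4 cytokines was 1.07 ± 0.929% in TAT-CRE mice (SD, n = 3) and 0.275 ± 0.0835% in PBS mice (SD, n = 2). Other splits of the mice gave a difference at least as large (exact permutation p = 0.4). Unthinned it was 1.85 ± 1.36% against 1.41 ± 0.0767% (exact permutation p = 0.7). Without TAT-CRE 208 the thinned difference of 0.793 percentage points became 0.371, and without TAT-CRE 215 it became 1.29. A cell without a UMI of a cytokine may still express it at this depth.

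Over all T cells no single gene passed the test, and the named genes are those of smallest unadjusted p. Higher in TAT-CRE mice was Ifit3, an interferon-induced antiviral protein (chromosome 19, 34583531 to 34588731), at 122 ± 47.5 CPM against 16.7 ± 1.05 CPM, a log2 fold change of 2.84 ± 0.50 (SE). Its near copy Ifit3b had 39 UMIs against 210 for Ifit3. Ifi27l2a, an interferon-inducible gene (chromosome 12, 103442167 to 103443680), stood at 406 ± 94.1 against 177 ± 17.7 CPM (log2 1.20 ± 0.26). Cxcl10, a chemokine that draws activated T cells (chromosome 5, 92346638 to 92348889), had 32, 46 and 5 UMIs against 1 and 1, a ratio of 34.2 with a counting interval of 9.17 to 287. Trim25, a ubiquitin ligase of antiviral signalling (chromosome 11, 88999376 to 89020293), stood at 55.5 ± 38.1 against 5.25 ± 3.89 CPM, and Ssr3, a translocon-associated protein (chromosome 3, 65379655 to 65392623), at 171 ± 43.0 against 61.7 ± 20.2 CPM. Lower in TAT-CRE mice were Cd160, a receptor of cytotoxic lymphocytes (chromosome 3, 96798763 to 96829351), at 14.0 ± 6.27 against 74.0 ± 5.68 CPM (log2 -2.36 ± 0.59), and Fcer1g, an adaptor of NK and innate-like T cells (chromosome 1, 171229572 to 171234365), at 6.36 ± 0.429 against 43.2 ± 29.3 CPM. NK cell markers, a list that holds Fcer1g, were at 372 ± 159 against 568 ± 131 CPM outside the ribosomal RNA genes (exact permutation p = 0.3). Lower too were Nemf, a ribosome quality control factor (chromosome 12, 69310522 to 69357165, log2 -2.86 ± 0.73), Zfc3h1, a factor of nuclear RNA decay (chromosome 10, 115384959 to 115432772, log2 -2.94 ± 0.81), and Asf1a, a histone chaperone (chromosome 10, 53596757 to 53609225, log2 -2.17 ± 0.61). For each of these 10 genes all TAT-CRE mice lay on one side of both PBS mice, which chance gives for 20% of genes not picked by p. These genes were picked for a small p in the same comparison, so their separation adds no support. By edgeR 0 of 6341 genes were called, with 230 at an unadjusted p under 0.05 (130 higher and 100 lower), and the adjusted p was 0.459 for Ifit3 and 0.999 for the other 9. DESeq2 called 1 gene, Ifit3 (adjusted p = 0.00712, and 0.000563 to 1.00 over its 16 alternatives). Without a filter on low counts edgeR called 6 genes, 4 higher and 2 lower. Among the higher ones were Ifit3, Cxcl10 (adjusted p = 0.00487) and Ifi27l2a (adjusted p = 0.0130). Among the lower ones was Ptgds (log2 -7.44, edgeR adjusted p = 0.0122), which the filter had kept out of the main test. It is named after its value was seen. Cxcl10 and Ifi27l2a were called in no other alternative over all T cells.

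Genes fixed in advance for T cell identity and function did not pass the test either. Cd4 stood at 127 ± 27.9 against 89.9 ± 14.2 CPM, Cd8a at 565 ± 177 against 536 ± 36.1 CPM and Cd8b1 at 430 ± 118 against 448 ± 67.1 CPM. Il2ra, the high-affinity interleukin 2 receptor chain carried by regulatory and activated T cells, stood at 49.9 ± 19.3 against 13.0 ± 9.89 CPM (log2 1.86 ± 0.71), above both PBS mice in 3 of 3 TAT-CRE mice. Foxp3 had 0, 15 and 23 UMIs against 0 and 4 (log2 3.12 ± 1.56). Ctla4, an inhibitory receptor, stood at 104 ± 29.6 against 81.8 ± 16.7 CPM. Gata3, the Th2 regulator, stood at 80.4 ± 23.4 against 105 ± 72.2 CPM, and Tbx21, the Th1 regulator, at 18.9 ± 8.50 against 25.6 ± 6.19 CPM. The edgeR adjusted p was 0.999 for each of these 8 genes. Il17a (6, 34 and 0 UMIs against 0 and 1), Ifng (0, 2 and 0 against 1 and 0), Csf2 and Il10 had too few UMIs to be tested.

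Of the type I interferon response genes, 13 of 15 tested members stood higher in TAT-CRE mice, with a median log2 fold change of 0.62 and a mean of 0.79. The camera test of limma called the list with the preset correlation (adjusted p = 4.32e-05 over 16 lists), and the call was lost with an estimated correlation (adjusted p = 0.920) and with fry (adjusted p = 0.950). Beside Ifit3 and Ifi27l2a these were led by Rsad2, the antiviral enzyme viperin, at 36.8 ± 23.0 against 6.62 ± 7.60 CPM, and Ifit1 at 143 ± 41.7 against 58.3 ± 0.506 CPM. Ifit1bl1, a near copy of Ifit1, had 321 UMIs against 295 for Ifit1. It had 90, 58 and 46 in TAT-CRE 207, 208 and 215 and 38 and 89 in PBS 216 and 218. Ifi203 (log2 -0.28) and Xaf1 (log2 -1.27) stood lower. None of the 15 was called over all genes, and 3 were called when adjusted over the list alone. Summed, the list stood at 3185, 3896 and 2076 CPM outside the ribosomal RNA genes in TAT-CRE 207, 208 and 215 and at 1840 and 2020 in PBS 216 and 218, that is 3052 ± 917 against 1930 ± 127 (exact permutation p = 0.2). The median was 0.39 without TAT-CRE 208 (adjusted p = 0.0134) and 0.94 without TAT-CRE 215 (adjusted p = 1.86e-08), and without the 87 cells of the cluster with the highest level of these genes, which was built on genes of the list, it was 0.116 (8 of 12 members higher, adjusted p = 0.321). With the preset correlation another split of the 5 mice, TAT-CRE 207 and 208 against the rest, gave a smaller unadjusted camera p (1.07e-10) than the real split (2.70e-06), and other splits called 0 to 6 lists against 1 in the real split.

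**Figure D2:**
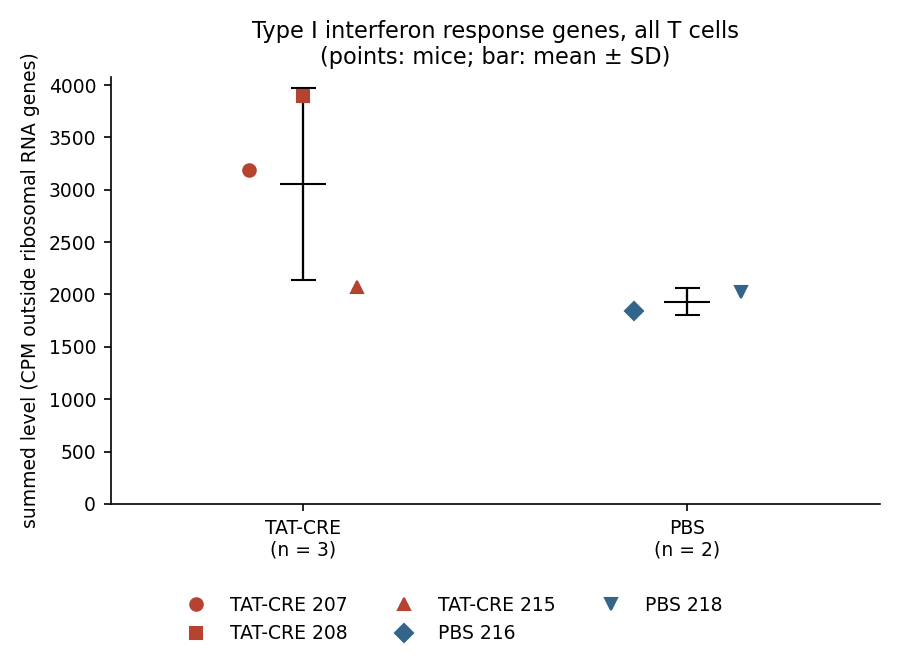
Summed level of the type I interferon response genes over all T cells, in CPM outside the ribosomal RNA genes; each point is 1 mouse, and lines with bars give the mean and SD of 3 TAT-CRE and 2 PBS mice. The TAT-CRE mice lie between 2076 and 3896 and the PBS mice at 1840 and 2020.

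None of the other 15 lists passed camera over all T cells. Closest were the interferon gamma response genes, of which 11 of 15 stood higher (adjusted p = 0.0634), and the naive and central memory genes, of which 9 of 12 stood lower (adjusted p = 0.0634). B2m (4132 ± 283 against 4155 ± 17.5 CPM) and H2-K1 (2621 ± 365 against 2461 ± 73.2 CPM), both of antigen presentation, are the most abundant of the first list. Tcf7 (411 ± 11.2 against 374 ± 88.5 CPM) and Il7r, the interleukin 7 receptor (350 ± 65.0 against 328 ± 144 CPM), are those of the second. Of the regulatory T cell genes 6 of 7 stood higher (adjusted p = 0.193), and of the inhibitory receptor genes 7 of 8 (adjusted p = 0.483), with Cd160 the exception and the only member called when adjusted over the list alone. Adjusted p was 0.474 for the glucocorticoid-responsive genes (5 of 8 higher; Txnip 731 ± 101 against 655 ± 103 CPM) and 0.474 for the adhesion and trafficking genes (6 of 16 higher; Itga4, which helps T cells cross brain vessels, 387 ± 228 against 451 ± 21.2 CPM). It was 0.823 for the Th1, tissue residency, cytotoxic effector, T cell activation, dissociation stress, cell cycle, glycolysis, mitochondrially encoded and cytosolic ribosomal protein genes. The chemokine gene Ccl5, shared by the Th1 and cytotoxic lists, stood at 2706 ± 1089 against 2595 ± 1221 CPM, Nkg7 of cytotoxic granules at 524 ± 120 against 540 ± 133 CPM, and Rgs1, a residency gene, at 416 ± 67.4 against 295 ± 137 CPM. Cd69 stood at 159 ± 28.0 against 120 ± 8.61 CPM, Junb at 364 ± 115 against 291 ± 26.6 CPM, Tubb5 at 136 ± 11.4 against 197 ± 26.4 CPM and Ldha at 196 ± 44.1 against 286 ± 65.3 CPM. Median and mean differ in sign for the Th1, T cell activation and glucocorticoid-responsive lists, and for the dissociation stress and cell cycle lists both are positive while the test points down. The encephalitogenic (Bhlhe40 and Tbx21), Th2 (Gata3 and Il1rl1) and Th17 (Rora) lists had fewer than 3 tested members and were not tested as lists. Adjusted over the list alone, no member of the other 17 lists was called. Several of these lists moved with single mice. The naive list was called lower without PBS 216 (adjusted p = 0.00203) and pointed higher without PBS 218 (0.876). The regulatory list was called higher without PBS 218 (0.0116) and had an adjusted p of 0.617 without TAT-CRE 215. The inhibitory receptor list was called higher without TAT-CRE 208 (0.0152) and pointed lower without TAT-CRE 207 (0.951) or PBS 218 (0.479). The cytotoxic list was called higher without PBS 216 (0.0482) and pointed lower without TAT-CRE 207 (0.102) or PBS 218 (0.191). The interferon gamma list was called higher without PBS 216 (0.0482), and the mitochondrially encoded list turned from lower to higher there (0.0169) and was called lower without PBS 218 (0.000306).

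Within CD4 T-like cells, Junb, a component of the AP-1 transcription factor (chromosome 8, 84974484 to 84978718), stood at 826 ± 186 against 314 ± 56.1 CPM (log2 1.38 ± 0.39), and Id2, a regulator of effector differentiation, at 1054 ± 112 against 487 ± 130 CPM (log2 1.07 ± 0.32). Ddx5, an RNA helicase, stood at 1732 ± 436 against 804 ± 197 CPM. Phf14, a chromatin reader, had 15, 14 and 19 UMIs against 0 and 0, at least 7.59-fold higher. Lower were Lef1, a transcription factor of naive T cells that was among the genes used for clustering (chromosome 3, 131110471 to 131224356, 99.5 ± 65.7 against 565 ± 19.2 CPM), and Bcl11b, a T cell identity factor (324 ± 38.9 against 742 ± 189 CPM). Also lower were Baz2a, a chromatin remodelling subunit (chromosome 10, 128091577 to 128129303, 19.9 ± 7.47 against 393 ± 83.0 CPM), Samhd1, which degrades nucleotides (log2 -2.38 ± 0.78), and Ostc of the glycosylation complex (log2 -3.18 ± 0.85). Nr3c1 had 8, 14 and 28 UMIs against 7 and 25, and Foxp3 0, 6 and 20 against 0 and 1, both also used for clustering. Adjusted over the list alone, Lef1 was called among the naive genes and Junb among the dissociation stress genes, a list that rises in cells handled during tissue dissociation. By edgeR 0 of 1407 genes were called, with 63 at an unadjusted p under 0.05; the adjusted p was 0.354 for Baz2a and 0.663 to 0.858 for the other 8 named here. The class rests on 23, 63 and 47 cells against 23 and 28, with 42124 to 111552 UMIs per mouse. It may be mixed, since 103 of its 184 cells lie in cluster 5, where Cd8b1 was seen about as often as Cd4. DESeq2 called 1 gene, Baz2a (adjusted p = 0.0336; 0.0336 to 1.00 over its 9 alternatives). Its log2 fold change was -4.23 with edgeR and ran from -4.46 to 0.12 over those alternatives, with the other sign without a mitochondrial limit. By edgeR 2 genes were called without PBS 218, Ppargc1b and Npm1, named after their values were seen.

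Within CD8 T-like cells, Cd160 had 2, 0 and 0 UMIs in TAT-CRE 207, 208 and 215 against 18 and 22 in PBS 216 and 218, a PBS over TAT-CRE ratio of 29.1 with a counting interval of 7.55 to 249. Fgl2, a secreted immunoregulatory protein (chromosome 5, 21372642 to 21378374), stood at 268 ± 66.4 against 620 ± 218 CPM, and Trbc2 (chromosome 6, 41546730 to 41548352) at 1612 ± 43.8 against 2389 ± 44.9 CPM. Lower too were the ubiquitin ligase gene Mycbp2 (log2 -1.95 ± 0.59) and Nsmce4a of the DNA repair complex SMC5/6 (log2 -3.49 ± 1.07). Higher were Nfkbia, the inhibitor of NF-kappa B (33, 3 and 20 UMIs against 0 and 0, at least 12.8-fold), and Luc7l3, a splicing factor (34, 21 and 2 against 0 and 0, at least 13.0-fold). Golga4, a Golgi tethering protein (chromosome 9, 118506267 to 118582519), stood at 363 ± 223 against 32.1 ± 19.0 CPM. Rasgrp1, an activator of Ras below the T cell receptor, had a ratio of 29.5 (counting interval 5.02 to 1193) and Dpm2 of mannosylation one of 11.9 (3.85 to 59.6). Cd160, Nfkbia, Trbc2, Nr3c1 and Ifi27l2a were among the genes used for clustering. Nr3c1 had 48, 7 and 12 UMIs against 25 and 17 (log2 0.00 ± 0.57). Adjusted over the list alone, Cd160 was called among the inhibitory receptor genes and Nfkbia among the glucocorticoid-responsive genes. By edgeR 0 of 1639 genes were called, with 40 at an unadjusted p under 0.05, and DESeq2 called 0; the edgeR adjusted p of the 10 genes was 0.997. The class rests on 98, 28 and 50 cells against 73 and 41, and without PBS 216 edgeR called 2 genes, Ifi27l2a and Malat1, named after their values were seen. Ifi27l2a had 78, 21 and 22 UMIs in the TAT-CRE mice, 31 in PBS 216 and 0 in PBS 218, so that call was made against a single mouse at 0, and without PBS 218 its log2 fold change was 0.57 (adjusted p = 0.999). No gene's treatment effect differed between CD4 T-like and CD8 T-like cells (edgeR, 0 of 2244 genes, 87 at an unadjusted p under 0.05, smallest adjusted p = 0.134).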

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

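Chosen after the results were seen were the alternatives without a mitochondrial limit, without the ribosomal RNA genes, with other gene sets for clustering, with thinned totals for the lists, with other settings for the lists within classes, and with TAT-CRE 208 and PBS 218 left out together. Of the comparisons of a main count, share or list call with an alternative, 88 were unchanged. Unchanged means the same number for a count and the same sign for a share. For the list call it means the same direction and side of the threshold. The fit on all kept cells is among the 88 and repeats the main fit, since no cluster was left out. Beside these, 14 counts moved, 9 shares changed sign and 2 list calls were lost, and the cause of these was not tested. The count of genes called over all T cells, 0 by edgeR, became 1 with DESeq2, 6 without a filter on low counts and 8 without TAT-CRE 208 and PBS 218; leaving out each mouse in turn gave 0 each time. In CD4 T-like cells it became 1 with DESeq2, 1 without the filter and 7 without TAT-CRE 208 and PBS 218, and leaving out 1 mouse gave 0 to 2 (2 without PBS 218, where the median of all genes moved by 0.40 on the log2 scale). In CD8 T-like cells leaving out 1 mouse gave 0 to 2 (2 without PBS 216), and DESeq2 gave 0. The CD8 T-like difference of -0.636 percentage points changed sign at 200 UMIs (7.13), at 800 UMIs (1.26), at resolution 0.6 (4.82), without the ribosomal RNA genes (1.11), and with clusters on genes of high residual variance (6.28) or on correlated genes (1.99). Without each mouse in turn it ran from -6.80 to 4.33; the CD4 T-like difference ran from 2.59 to 9.29, that of Foxp3 cells from 0.506 to 1.19 and that of cytokine cells from 0.371 to 1.29. The count of lists called, 1, became 0 with an estimated correlation, 0 with fry and 2 without TAT-CRE 208 and PBS 218, and ran from 1 to 5 over the single mice left out (2 without TAT-CRE 208, 3 without PBS 218, 5 without PBS 216). The type I interferon list had an adjusted p of 0.920 with an estimated correlation and 0.950 with fry, against 1.86e-08 (without TAT-CRE 215) to 0.0134 (without TAT-CRE 208) with 1 mouse left out. The mitochondrially encoded list, lower in the main test, was called higher without PBS 216 (adjusted p = 0.0169), and its adjusted p ran from 0.000306 (without PBS 218) to 0.951 (without TAT-CRE 207). Where a single PBS mouse was left, it was assumed to vary like the TAT-CRE mice. Named genes had a sign other than the main one in 59 of 788 comparisons over all T cells, 61 of 490 in CD4 T-like and 75 of 511 in CD8 T-like cells, and lists called neither in the main test nor in the alternative had one in 30 of 202. No CD4 T-like cluster could be named at 800 UMIs or with the other gene sets, and no CD8 T-like cluster on variable genes, so these have no value. At the depth, number of mice and spread of these libraries, simulated counts gave a call for 10.4% of genes changed 2-fold over all T cells.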

Other observations

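Tests added after the data were seen are those of lists within the classes and that of T cell marker RNA in TAT-CRE 208. Within CD8 T-like cells the cytosolic ribosomal protein genes stood higher in TAT-CRE mice for 70 of 102 members, with a median log2 fold change of 0.17 (camera with a preset correlation, adjusted p = 0.0317 over the 14 lists of that class). That call was lost with an estimated correlation (adjusted p = 0.732) and when adjusted over the 28 lists of both classes (adjusted p = 0.0635). The same list in CD4 T-like cells had a median of -0.02 (adjusted p = 0.757) and over all T cells one of -0.03 (adjusted p = 0.823); the difference between the classes was not tested. No other list passed within either class. The naive and central memory genes had a median of -0.04 in CD4 T-like cells (adjusted p = 0.147) and of 0.72 in CD8 T-like cells (adjusted p = 0.163). The adhesion and trafficking genes stood lower for 9 of 11 members in CD4 T-like cells (voom values, median -0.55, camera adjusted p = 0.147). Itga4, a gene used for clustering, was among them at 225 ± 118 against 646 ± 225 CPM. All 12 naive and central memory genes and 16 of the 17 adhesion and trafficking genes had been used for clustering. These list comparisons are therefore made within classes built on the same genes.

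Il17a and Il17f, cytokine genes of Th17 and gamma delta T cells, were seen in few cells, and their spread over the mice was not tested. Of 41 UMIs of Il17a, TAT-CRE 208 held 34, in 8 of its 303 cells (2.64%, 95% interval 1.15 to 5.14), and it had no cell with Il17f, which allows a share of cells with a UMI up to 0.990%. TAT-CRE 207 had Il17f in 6 of 311 cells (1.93%, 0.711 to 4.15) and Il17a in 1. The PBS mice had Il17f in 3 cells each and Il17a in 0 and 1.

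Type I interferon response genes had a median log2 fold change of 0.62 in TAT-CRE mice, a difference called with camera's preset correlation and not with an estimated one (adjusted p = 0.920). Without the ribosomal RNA genes, whose share differed between the mice, the median was 0.550 (adjusted p = 5.52e-05 by camera with the preset correlation). The main test already scaled the totals by TMM, so leaving these genes out could change little. A cause that goes with that share stays open. The cluster with the highest level of these genes held 9.97%, 7.92% and 5.03% of cells in the TAT-CRE mice and 3.72% and 2.19% in the PBS mice (exact permutation p = 0.2), and without its 87 cells the median was 0.116 (adjusted p = 0.321), so the difference may lie in few cells; but that cluster was built on genes of the list, and removing it removes high cells by construction. Whether the mix of CD4 T-like and CD8 T-like cells contributes stays open too, with medians of 0.0976 and 0.657 over only 4 members in each class. The clusters behind these classes were also built on 16 of the 17 genes of the list. Of the 10 splits of the 5 mice, 2 gave a camera p as small, and 10 are too few for a share under 0.05. Other splits called up to 6 lists, which a structure of the samples or too small a preset correlation would each give. The real split had a -log10 p of 5.57, and that of TAT-CRE 207 and 208 against the other mice 9.97. The latter follows the age of 18 weeks shared by those 2 mice and no PBS mouse. At 19 weeks TAT-CRE 215 and PBS 216 had 2076 and 1840 CPM. The list was not tested with age as a covariate. For single genes over all T cells edgeR with age as a covariate called 0 genes, as did the main test.

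TAT-CRE 208 had few cells with a Cd8a or Cd8b1 UMI, 25.7% against 42.6% to 59.2% in the other mice, and it is the shallowest library. Fewer UMIs per cell are argued against as the whole cause: with cells thinned to 400 UMIs outside the ribosomal RNA genes its share was 20.9% (95% interval 16.0 to 26.1), below the 29.6% to 42.5% of the others. As a list its T cell markers stood at 8181 CPM, within the 7964 to 9395 of the others. That sum leans on Trbc1, which had 367 UMIs in this shallowest library against 232 to 363 in the others. Its near copy Trbc2 had 493 UMIs against 614 to 1078. These counts are not scaled for depth, and this library had 259756 UMIs outside the ribosomal RNA genes against 301010 to 470720. Whether T cell RNA other than Trbc1 was lower in this mouse therefore stays open. A different makeup of the T cells in this mouse is a candidate explanation that stays open and untested, as does a difference in the sort. The plate and amplification batch of TAT-CRE 208 held no other mouse, so an effect of these cannot be told apart from either.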
